A study of Mus musculus with 2 samples.

How the data were processed

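RNA sequencing of mouse heart was compared between an animal given a mimic of CHAPIR, a heart piRNA, and an animal given a scrambled negative control (NC) mimic. PIWI-interacting RNAs (piRNAs) are small RNAs best known from the germline. The mice were of the C57BL/6 strain, and the CHAPIR mimic was given at 30 mg/kg from an implanted osmotic minipump over 14 days, per the labels' protocols. No dose of the NC mimic is recorded in the sample information used here, so equal dosing could not be checked. Total RNA was extracted with Trizol, fragmented, reverse transcribed with random primers and made into libraries with a dUTP second strand, per the labels' protocols. Each group held 1 library.

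The deposited table gave 1 value per Ensembl transcript and library, treated here as FPKM (fragments per kilobase of transcript, scaled to library size) computed by the authors. Neither the labels nor the table header named the unit, and it was inferred from the values. Values times transcript length in kilobases summed to 739668 in the CHAPIR library and 732588 in the NC library, below the upper limit that FPKM allows. If the values were TPM instead, every ratio would change by 1 constant factor per library. Cutadapt, HISAT2 2.0.5, StringTie and STAR 2.5.2b and the build GRCm38 were named in the submitters' processing notes, without their roles. The annotation the authors used was not given in the sources used here. The table listed 23178 transcripts, and the smallest value of the higher library was 0.5, so transcripts below that level in both libraries were not analysed here. No read counts were used and whole-read steps were not found in the values, so the depth of the libraries is unknown and no counting interval is given.

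Transcripts were matched by identifier, without the version, to GENCODE M21 on the same build. Of these, 23128 matched, 21972 of them with the same version, 50 did not match and were left out, and 23061 of those matched were protein coding. Values of the listed transcripts of a gene were summed, which gave 12395 genes, of which 6731 had 1 listed transcript. Gene coordinates are those of GENCODE M21, 1-based. How the reads of near-identical copies were shared between them is not given in the sources used here, so values of the Gbp, Irg, Ifit, Oas and H2 families are uncertain for single members.

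The log2 ratio of a gene is log2 of (CHAPIR + 1) minus log2 of (NC + 1), which understates the change of genes with low values. Genes at 1 or more in at least 1 library were counted at a 2-fold threshold. With 1 library per group there is no test, no p-value and no standard error, and nothing measures the spread between animals. As a description of each single gene, the share of the 500 genes nearest in mean expression with an absolute log2 ratio at least as large is given. An exact 0 in the table can be a failed estimate, so such genes are given as listed at 0, with no fold.

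A set of 54 gene lists (pathways, complexes, families and cell type markers) was fixed before the data were examined, as were the design, the named-gene rule and the alternatives, except those said to be chosen later. Members with a mean of at least 1 FPKM were measured. The median log2 ratio of each list with at least 5 measured members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list below the percentile 2.5 or above 97.5 is described as standing apart, and members were counted at a 1.5-fold threshold. Percentiles describe these 2 libraries and are not p-values. Of the 44 lists with a percentile, 2.2 would lie outside by chance if genes varied independently. Genes of a list can vary together and lists share members, so more than that may lie outside between any 2 hearts.

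The genes named are those of the target axis, the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 5 FPKM (predicted gene models and pseudogenes were counted but not named, 4 among the highest and 3 among the lowest), the 2 highest and 2 lowest members of each list, all measured hypertrophy markers, the Parp family members at 1.5-fold and the sex-linked genes. Other list members are named as examples chosen after their values were seen. Some single-gene values that fall under the rule are not reported here.

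The alternatives were pseudocounts of 0.1 and 5, other filters on low values, centring of the log2 ratios, quantile normalization, rescaling without mitochondrially encoded genes and the 50 most abundant genes, and the most abundant transcript of each gene in place of the sum. The comparison was tested on simulated data made from the mean of each of the 12395 genes. Normal noise was scaled to the median absolute deviation of the real log2 ratios in each expression bin, which leaves out their tails. Of 100 genes changed by 1.5 log2 units, 96% were recovered at the 2-fold threshold, and of 100 changed by 3 units, 100% were. Of 200 unchanged lists of 20 genes, drawn from 11110 genes, 6% fell outside the central 95% of random lists, and of 50 lists shifted by 0.3 log2 units 100% did. In the simulation 0 of 11039 unchanged genes passed 2-fold. The simulated noise has no heavy tails and is independent between genes. These values therefore do not give the share of false 2-fold differences, or of lists outside by chance, in the real libraries. Recovery of changed genes may be lower there. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.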

Results

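Hearts of 2 mice were profiled by RNA sequencing after 2 weeks of a mimic of the heart piRNA CHAPIR or of a scrambled negative control (NC) mimic. Each group held 1 library, so there are no replicates, and every difference below describes these 2 libraries and has no replicate check. The summed transcript values were 401938 in the CHAPIR library and 394675 in the NC library, and mitochondrially encoded genes made up 34.1% and 32.2% of the summed gene values. Across the 11416 genes at 1 FPKM or more in at least 1 library, log2 values of the libraries had a Pearson r of 0.967 and a Spearman rho of 0.955, across genes, which are not independent replicates. The spread of single-gene log2 ratios was wider at low expression, with an SD of 0.46 among genes with a mean of 1 to 5 FPKM and 0.32 among those at 100 FPKM or more.

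The hearts also differed in Y-linked transcripts. Ddx3y (21.6 FPKM), Eif2s3y (22.1), Uty (6.41) and Kdm5d (1.45) were present in the CHAPIR library and listed at 0 in the NC library. Their X-linked counterparts Eif2s3x and Ddx3x, 2 of the genes known to escape X inactivation, were lower in the CHAPIR library, at 21.6 against 36.7 FPKM and 52.5 against 64.9 FPKM, and Kdm5c was at 6.202 against 9.28 FPKM. Sex of the animals is not given in the labels used here. These values are the pattern of a male heart in the CHAPIR library and a female heart in the NC library. Apparent sex and mimic therefore differed together, and no difference below can be assigned to the mimic rather than to sex. The mimic itself was not measured in the table, so no value checks which library received it or excludes a mixed-up sample.

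The first comparison concerns the molecules through which CHAPIR has been studied in cardiac hypertrophy, in which the piRNA is linked to the N6-methyladenosine writer Mettl3 and to Parp10, a mono-ADP-ribosyltransferase. Parp10 (chromosome 15, 76231174 to 76243441) was at 10.7 FPKM in the CHAPIR library and 6.39 FPKM in the NC library, a log2 ratio of 0.67, and 8.2% of genes of like expression had a ratio at least as large. Mettl3 (chromosome 14, 52294841 to 52305128), the catalytic subunit of the methyltransferase, was at 4.96 against 2.31 FPKM, a log2 ratio of 0.85 and a share of 4.8%. The kinase Gsk3b was at 9.53 against 9.86 FPKM, and Nfatc4, a calcineurin-responsive transcription factor, at 1.21 against 1.49 FPKM, both with ratios smaller than those of most genes of like expression. Parp10 rested on 2 listed transcripts that went opposite ways. ENSMUST00000075689.6, with 11 exons, was at 6.57 against 0.94 FPKM, and ENSMUST00000165738.7, with 10 exons, at 4.17 against 5.45 FPKM, so the log2 ratio of Parp10 was -0.32 when only its most abundant transcript was used. Only 1 of the 15 annotated transcripts of Mettl3 was listed.

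**Figure D1:**
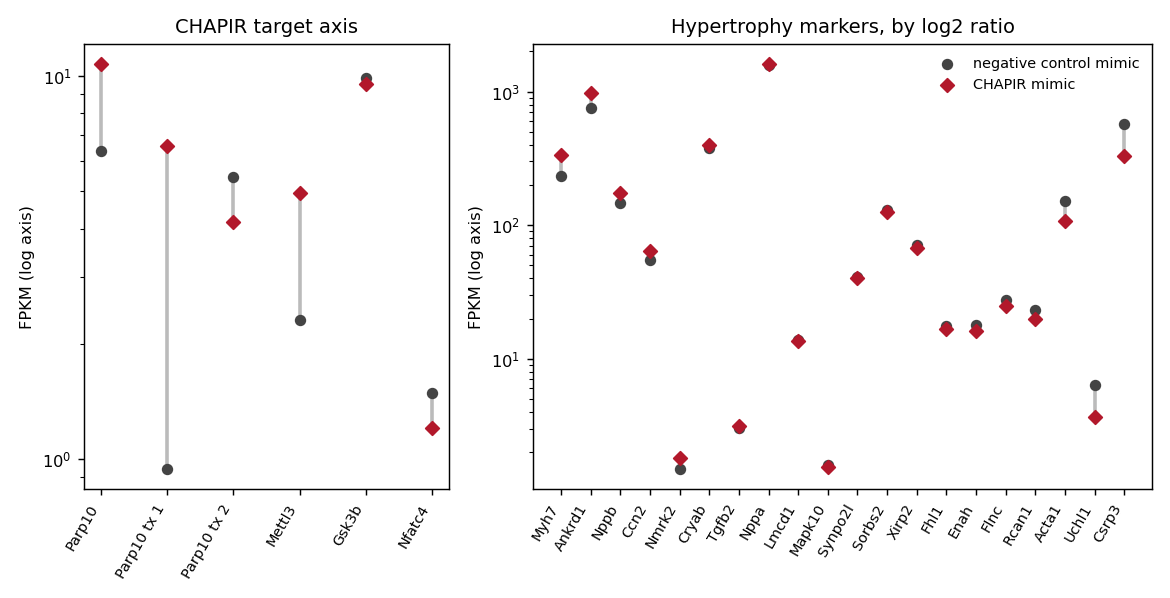
FPKM values (log axis) of the target axis genes and of 20 hypertrophy markers in the NC library (circles) and the CHAPIR library (diamonds), 1 library each, with a line joining both values of a gene. The 2 Parp10 transcripts (tx 1, ENSMUST00000075689.6, and tx 2, ENSMUST00000165738.7) lie on opposite sides, and Csrp3, Acta1 and Uchl1 are lower in the CHAPIR library while Myh7 and Ankrd1 are higher.

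The Parp family held 6 of 18 measured members at 1.5-fold or more, all higher in the CHAPIR library. Parp8 was at 7.01 against 1.19 FPKM, Parp14 at 20.05 against 8.08, Parp9 at 15.4 against 8.30, Parp12 at 14.99 against 9.12, and the hydrolase Adprhl2 at 3.06 against 1.64 FPKM, with Parp10 the remaining member. Parp9, Parp12 and Parp14 are also on the interferon-stimulated list. Of the 67 measured members of the interferon lists described below, 10 had a log2 ratio below that of Parp10. The ratio of Parp10 thus lay within the range of those lists and cannot be told apart from that wider difference. The lowest members were Macrod1 (87.1 against 105 FPKM) and Parp16 (1.27 against 1.62 FPKM), and the list median of 0.10 lay at the percentile 91.5 of random lists. Among N6-methyladenosine genes, Mettl3 was the 1 member of 18 at 1.5-fold, Ythdf3 followed at 19.5 against 15.98 FPKM, and the median of -0.00 lay at the percentile 45.3.

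Markers of cardiac hypertrophy did not move together. The median log2 ratio of the 20 measured markers was -0.03, at the percentile 51.8, with 0 higher and 2 lower at 1.5-fold. Myh7, the slow myosin heavy chain of the fetal heart, was at 335 against 234 FPKM, and the ratio of Myh7 to the adult isoform Myh6 was 9.17% in the CHAPIR library and 5.67% in the NC library. Ankrd1, a stretch-responsive cofactor, was at 983 against 756 FPKM. The natriuretic peptide genes Nppb and Nppa were at 173 against 146 FPKM and 1603 against 1583 FPKM. Csrp3, a Z-disc mechanosensor, was lower, at 329 against 576 FPKM, as were skeletal actin Acta1 (108 against 153 FPKM) and Uchl1 (3.64 against 6.35 FPKM). Rcan1, a calcineurin target, was at 19.7 against 23.2 FPKM. Log2 ratios of the other markers, Xirp2, Fhl1, Nmrk2, Enah, Flnc, Ccn2, Tgfb2, Mapk10, Lmcd1, Sorbs2, Synpo2l and Cryab, lay between -0.16 (Flnc) and 0.21 (Ccn2). Sarcomere genes (median -0.06), ion handling genes (-0.05), the calcineurin, NFAT and GSK3 list (-0.04) and cardiomyocyte markers (-0.09) also lay inside the central 95% of random lists.

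The second comparison was made across all genes. Of the 11416 genes, 294 (2.58%) were at least 2-fold higher in the CHAPIR library and 152 (1.33%) at least 2-fold lower, and 37 and 14 passed 4-fold. Interferon list genes made up 42 of the 294 and 0 of the 152, out of 67 tested. Among the 12 highest named genes were the Y-linked Eif2s3y and Ddx3y, the guanylate-binding proteins Gbp4 (16.7 against 0.21 FPKM) and Gbp10 (51.3 against 5.01), the immunity-related GTPases Igtp (204 against 31.9), Irgm1 (138 against 21.96) and Iigp1 (320 against 57.2), Xaf1 (22.3 against 3.28) and the platelet basic protein gene Ppbp (14.7 against 1.68). The remaining 3 were Mipep, a mitochondrial peptidase, at 18.9 against 0.64 FPKM, the cyclin gene Ccnl2 at 11.2 against 0.42 and Osbpl9 at 41.0 against 5.34 FPKM, for which 1 of 5, 1 of 5 and 5 of 19 annotated transcripts were listed.

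The lowest named genes were led by Scd1, the stearoyl-CoA desaturase (5.44 against 47.1 FPKM), carbonic anhydrase Car3 (6.37 against 49.97 FPKM) and the adipocyte hormone gene Adipoq (1.35 against 9.87 FPKM). Fasn, fatty acid synthase, was at 2.38 against 9.43 FPKM. Alas1, the first enzyme of heme synthesis outside red cells, was at 12.6 against 46.8 FPKM, and Aldh6a1 at 8.52 against 35.7 FPKM. Rer1 (7.94 against 39.5 FPKM), the deubiquitinase Usp7 (3.48 against 17.7), Lrrfip2 (8.22 against 32.1), Ptms (13.6 against 51.2), the potassium-chloride cotransporter Slc12a7 (4.54 against 17.2) and Shld1 (5.15 against 18.6 FPKM) completed the 12. A single transcript was listed for Scd1, Car3 and Rer1, each out of 3 annotated, for Adipoq out of 2, Fasn out of 6, Ptms out of 5, Slc12a7 out of 11 and Usp7 out of 13. The 2-fold counts moved with the pseudocount, to 507 higher and 267 lower at 0.1 and to 80 and 29 at 5. With the most abundant transcript of each gene in place of the sum, they were 611 and 422.

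**Figure D2:**
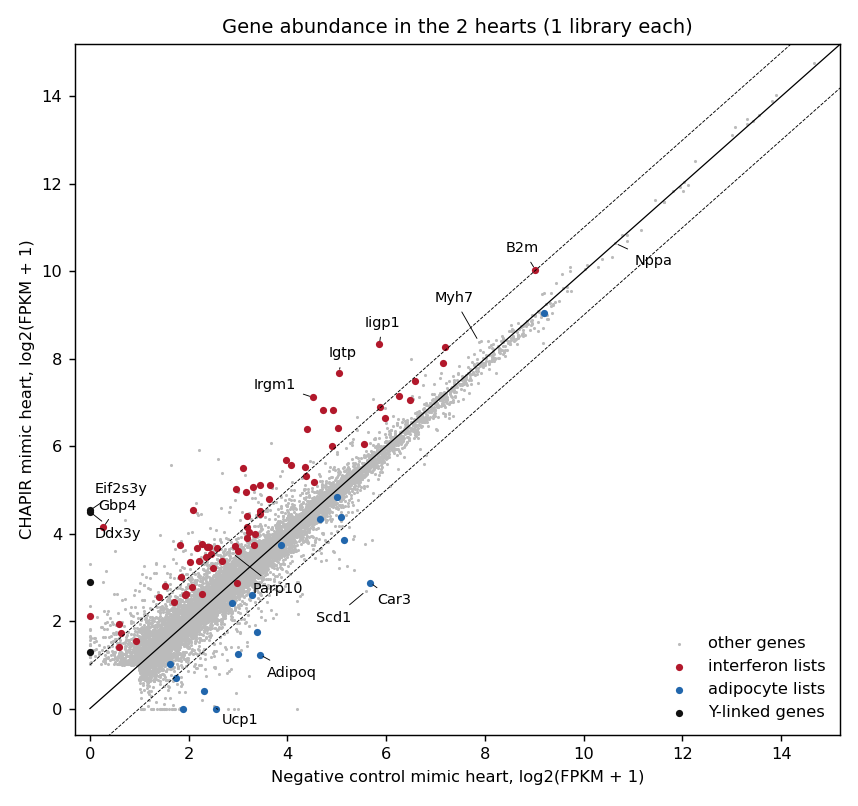
Gene abundance in the NC library (x axis) and the CHAPIR library (y axis) as log2(FPKM + 1), 1 library each, with genes of the interferon lists in red, of the adipocyte lists in blue and Y-linked genes in black. The solid line marks equal values and the dashed lines a 2-fold difference. Of the 67 interferon list genes 42 are at least 2-fold higher in the CHAPIR library, and Adipoq, Car3 and Scd1 lie below the lower dashed line.

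Interferon-stimulated genes and genes of interferon gamma response and antigen presentation were higher as groups in the CHAPIR library. In the interferon-stimulated list, 33 of 37 measured members were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 1.11, at the percentile 100 of random lists. Ifit1, an RNA-binding antiviral protein, was at 44.4 against 7.54 FPKM, and the ubiquitin-like Isg15 at 29.8 against 7.97 FPKM. The lowest members were Dtx3l (6.32 against 6.85 FPKM) and Trim25 (12.4 against 9.05 FPKM). In the interferon gamma and antigen presentation list, 29 of 30 were higher and 0 lower, with a median of 1.13, also at the percentile 100. B2m, the light chain of MHC class I, was at 1045 against 519 FPKM, the immunoproteasome subunit gene Psmb8 at 33.5 against 11.5, and the MHC class II gene H2-Ab1 at 118 against 57.5 FPKM. The lowest were Tap2 (5.19 against 3.81 FPKM) and Socs1 (1.92 against 0.90 FPKM). Both lists stood apart under every alternative that could move them, except that the second had too few members among genes with 1 annotated transcript. Centring of the log2 ratios shifts all genes alike and cannot change a percentile.

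Macrophage markers and inflammatory genes were higher alongside them. All 12 macrophage markers were higher, 7 of them by 1.5-fold, with a median of 0.69 at the percentile 100, led by the Fc receptor gene Fcgr1 (3.19 against 1.05 FPKM) and the complement gene C1qb (82.4 against 41.7 FPKM). Lyve1 (10.9 against 8.35 FPKM) and Cd163 (6.84 against 5.07 FPKM), markers of resident macrophages, were the lowest. Of the neutrophil, T and NK cell, and B cell lists only 2 of 10, 2 of 12 and 1 of 9 markers were measured, too few for a percentile. The neutrophil genes S100a9 and S100a8 were at 15.1 against 2.93 FPKM and 7.496 against 2.07 FPKM, the cytotoxic lymphocyte genes Nkg7 and Gzmb at 3.23 against 1.05 and 1.46 against 0.73 FPKM, and the plasma cell gene Jchain at 9.50 against 5.35 FPKM. Acute phase and complement genes had 15 of 21 members higher and 1 lower (median 0.70, percentile 100). Saa3 was at 8.90 FPKM and listed at 0 in the NC library, the protease inhibitor gene Serpina3n was at 15.4 against 3.20 FPKM, and the exception was Cfd, which fat cells secrete, at 13.5 against 34.3 FPKM. Inflammatory cytokine and NF-kB genes had 11 of 20 higher and 1 lower (median 0.59, percentile 100), led by the chemokine genes Cxcl1 (6.34 against 1.03 FPKM) and Ccl7 (7.61 against 1.47 FPKM). Nfkb1 was lower, at 5.36 against 9.53 FPKM, but its log2 ratio was 0.53 with the most abundant transcript only.

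Immediate early genes, which respond within minutes to many stimuli, had 12 of 18 members higher and 0 lower at 1.5-fold (median 0.81, percentile 100). Fos was at 20.7 against 3.77 FPKM and Atf3 at 8.51 against 1.14 FPKM, and the lowest members, Jund and Ccn1, were at 39.5 against 33.4 and 30.7 against 24.3 FPKM. In the glucocorticoid response list 6 of 20 members were higher and 1 lower (median 0.36, percentile 100), and of the 6 Lcn2 and Cebpd are also on the acute phase list and Dusp1 on the immediate early list. Lcn2 was at 3.84 against 0.64 FPKM and Errfi1 at 11.6 against 4.36 FPKM, while Angptl4 was lower at 1.57 against 3.56 FPKM. Platelet and red cell markers were higher (median 0.37, percentile 100), with Gp9 at 6.42 against 0.19 FPKM, and the median was 2.10 over the platelet genes and 0.31 over the red cell genes.

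Matrix genes had 6 of 37 members higher and 0 lower at 1.5-fold (median 0.23, percentile 100). The collagen cross-linking enzyme gene Lox was at 2.58 against 0.85 FPKM and Col3a1 at 66.7 against 37.4 FPKM, while Col15a1 was at 12.7 against 18.5 FPKM and Col8a1 at 3.99 against 5.74 FPKM. Fibroblast markers (median 0.19, percentile 99.9) were led by Col1a1, at 21.4 against 13.7 FPKM, but the markers of activated fibroblasts lay inside the random range (median -0.10, percentile 14.1), with Acta2 at 72.2 against 99.5 FPKM and Postn at 26.4 against 21.9 FPKM. The median of the matrix list lay at the percentile 83.1 among genes with 1 annotated transcript, an alternative chosen after seeing the data, and that of fibroblast markers at 93.7 with the most abundant transcript only.

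Adipocyte markers were lower in the CHAPIR library. Of 11 measured white adipocyte markers, 8 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -1.62, at the percentile 0. Beside Adipoq, Car3 and Fasn, the lipid droplet genes Plin1 (0.32 against 3.98 FPKM) and Cidec (1.38 against 6.95 FPKM) were lower, and the adipokine gene Retn was listed at 0 against 2.69 FPKM. The exceptions were Lipe, the hormone-sensitive lipase (12.3 against 13.7 FPKM), Plin4 (27.6 against 30.9 FPKM) and Pparg (4.36 against 6.34 FPKM). Of 6 brown adipocyte markers 4 were lower and 0 higher (median -0.63, percentile 0). Ucp1, the uncoupling protein of brown fat, was listed at 0 in the CHAPIR library and at 4.91 FPKM in the NC library, and Cidea was at 19.8 against 32.9 FPKM. The smallest differences were those of Cox8b (532 against 585 FPKM) and Ppargc1a (19.1 against 24.4 FPKM). Cox8b is also on the oxidative phosphorylation list and Ppargc1a on the mitochondrial biogenesis list. Cidea, Cox8b and Ppargc1a stayed present where Ucp1 was listed at 0, so the list median may not describe brown fat alone.

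Genes of energy metabolism had small and mostly negative log2 ratios. The median was -0.17 for the citric acid cycle, in which 0 of 19 genes had a positive log2 ratio, -0.15 for glycolysis, -0.14 for nuclear-encoded oxidative phosphorylation subunits, -0.13 for fatty acid oxidation and -0.12 for mitochondrial biogenesis, at percentiles of 0.89, 0.73, 0.47, 2.31 and 1.96. A part of this is general, since all genes with a mean of 100 FPKM or more had a median of -0.07. The matched random lists had medians of -0.07, -0.05, -0.07, -0.06 and -0.01, in the same order. Examples are Pgk1 (81.9 against 129 FPKM), Acsl1 (147 against 205 FPKM), Atp5d (205 against 297 FPKM) and Dlst (40.3 against 54.0 FPKM), while Pdk4, an inhibitor of pyruvate oxidation, was at 139 against 101 FPKM. Mitochondrially encoded genes had a median of 0.11 at the percentile 99.7, with mt-Nd4 at 10137 against 8565 FPKM. Each of these 6 lists fell inside the random range under at least 1 alternative. Under quantile normalization the median of the mitochondrially encoded genes was 0 at the percentile 73.2.

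**Figure D3:**
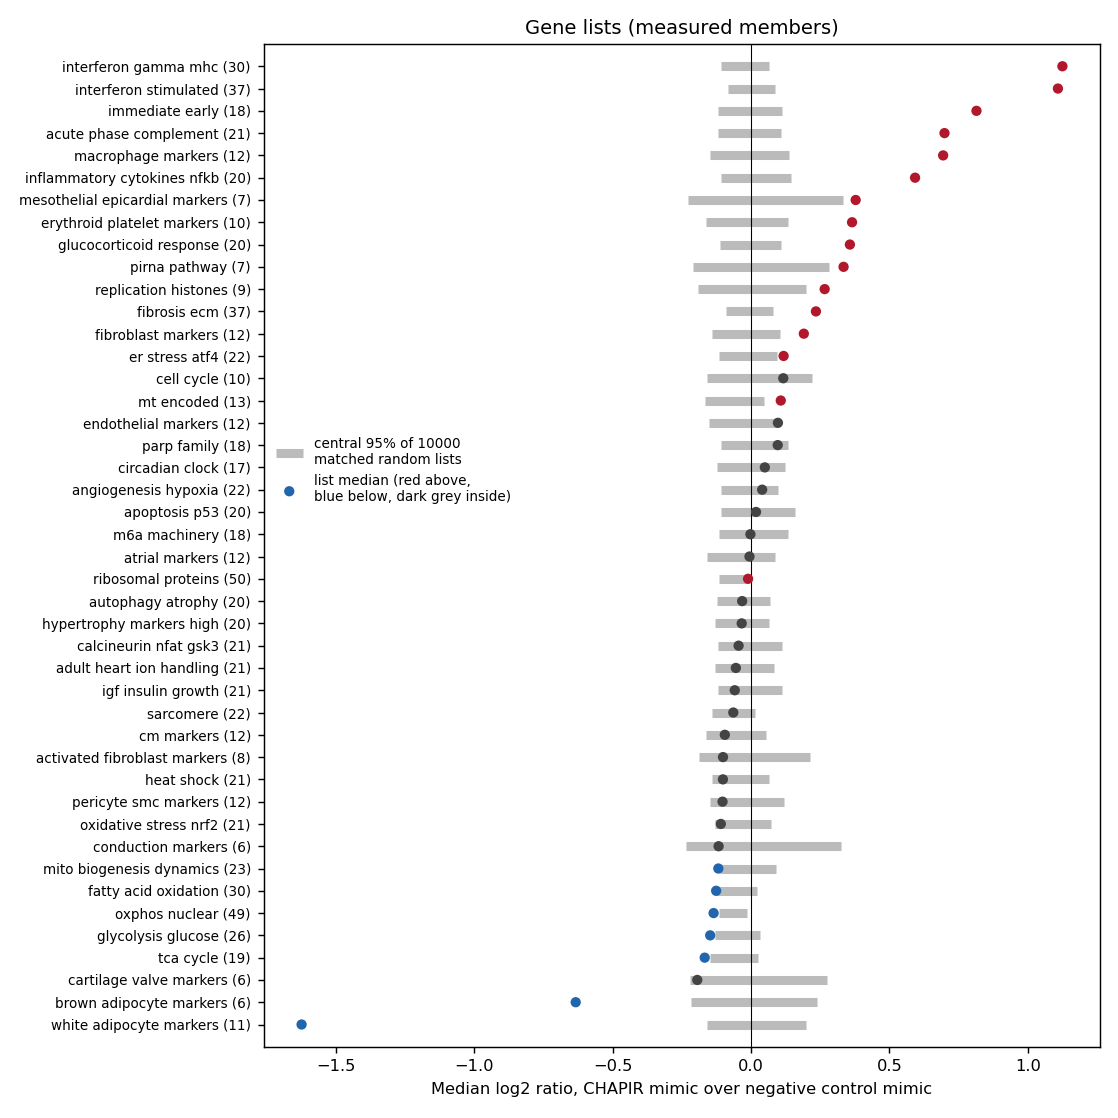
Median log2 ratio of CHAPIR over NC (x axis) of each gene list with at least 5 measured members (y axis, number of measured members in brackets), with grey bars for the central 95% of 10000 random lists matched on expression. Of the 44 lists, 16 lie above the bars and 7 below, and the 2 interferon lists (1.11 and 1.13) and the white adipocyte list (-1.62) lie at the extremes.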

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

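No paired analysis was possible because each group held 1 library. Depth is unknown and sets no stated limit. Alternatives chosen after seeing the data were those without Y-linked genes, without interferon list genes or members, with 1 annotated transcript, and the rescaled lists. Of 11416 genes, 294 were 2-fold higher and 152 lower. These became 507 and 267 at a pseudocount of 0.1, 80 and 29 at 5, 140 and 51 at a mean of at least 5 FPKM, 611 and 422 with the most abundant transcript only, and 36 and 8 among 1040 genes with 1 annotated transcript, where fewer genes were tested. Both counts stayed within 1.5 times in the other 6 alternatives (290 higher without Y-linked genes, 252 without the interferon lists). Lists above numbered 16 and lists below 7. With 1 annotated transcript, 10 lists could be measured, of which 4 lay above and 0 below, and 4 lists lay below with the most abundant transcript only. The median of ribosomal protein genes, -0.01, became 0.0173 with quantile normalization and 0.0021 when rescaled. With the most abundant transcript only, the log2 ratio of Parp10 became -0.32, Bcl2l1 -0.20 and Nfkb1 0.53, because only 1 transcript was then read. Pearson r was 0.942 at a pseudocount of 0.1. The cause of the other changes was not tested. Over the settings tried, 796 values of the other named genes reported moved by less than the SD of genes of like expression and 90 by more. Of list medians, 355 moved by less than the SD of random lists and 43 by more.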

Other observations

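Further lists had medians outside the random range with few members at 1.5-fold. A list of piRNA pathway and Argonaute genes had 0 of 7 measured members at 1.5-fold and a median log2 ratio of 0.33 (percentile 98.7, or 87.8 with the most abundant transcript only). Of these members 4 were Ago1, Ago2, Ago3 and Ago4, Argonautes of the microRNA pathway, so the median does not describe piRNA factors alone. The piRNA factors were Mov10l1 (22.2 against 14.9 FPKM), Tdrd7 (6.01 against 4.35 FPKM) and Tdrkh (2.01 against 2.16 FPKM), and Ago4 was at 2.52 against 2.74 FPKM. Mesothelial markers had 2 of 7 higher and a median of 0.38 (percentile 98.6), with Upk1b at 3.26 against 1.55 FPKM and Msln at 6.70 against 3.80 FPKM, and the percentile was 97.1 at a pseudocount of 5. In the replication histone list (0.27, percentile 99.3), 1 of 9 members was higher at 1.5-fold, Hist2h2aa1, at 21.3 against 3.49 FPKM. The endoplasmic reticulum stress list had 1 of 22 members higher and 1 lower, with a median of 0.12 (percentile 98.8), although its chaperone gene Hspa5 was lower, at 47.5 against 108 FPKM, and Mthfd2 was at 2.03 against 0.42 FPKM. The percentile of this list was 96.6 with no filter on low values and 85.2 among genes with 1 annotated transcript. Ribosomal protein genes had 1 of 50 members higher and a median of -0.01 (percentile 98.0), against -0.07 over the matched random lists. The list median turned positive under quantile normalization and rescaling. Its percentile was 97.0 at a mean of at least 5 FPKM and 96.65 with the most abundant transcript only.

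Some single genes inside lists that did not stand apart differed by 1.5-fold or more. Gpx3, a secreted glutathione peroxidase, was at 254 against 89.5 FPKM and Prdx1 at 53.3 against 81.5 FPKM. Bmp10, an atrial growth factor, was at 101 against 41.4 FPKM. The smooth muscle gene Tagln was at 24.2 against 39.2 FPKM, Pgf was at 3.97 against 1.55 FPKM and Smoc2 at 18.4 against 33.0 FPKM. The remaining lists, with medians inside the random range, were heat shock (-0.10), oxidative stress (-0.11), circadian clock (0.05), cell cycle (0.12), apoptosis (0.02), autophagy (-0.03), angiogenesis (0.04), insulin and IGF (-0.06), atrial (-0.01), conduction (-0.12), endothelial (0.10), pericyte and smooth muscle (-0.10) and valve (-0.19) genes. Of the lists with fewer than 5 measured members, those for lung airway and thymus had 0, skeletal muscle (Tnni2 0.66 against 1.67 FPKM) had 3, Schwann cells and neurons (Ncam1 1.33 against 2.22 FPKM) had 4 and liver (Trf 21.04 against 14.5 FPKM, Cyp2e1 4.58 against 6.03 FPKM) had 2.

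In the weighing that follows, the tests on near-identical copies, the sex of the hearts and lipid synthesis were chosen only after the result was seen. Those on leukocytes, fat tissue and transcript assignment were written before. The verdicts of the leukocyte and fat tissue tests were changed afterwards, for the reasons given with them. The first pattern is the higher interferon genes. More leukocytes in general as the whole cause would raise 14 pan-leukocyte genes by as much, but the median log2 ratio was 1.11 for 67 interferon genes and 0.74 for the leukocyte genes, a difference of 0.374 (95% bootstrap interval over genes 0.047 to 0.684). Other heart cells may express some of the 14, such as Cyba (29.5 against 25.9 FPKM), and hide a part of a rise of leukocytes. The interval also does not measure the spread between animals. A limit written before the values were seen, a difference above 0 with an interval that excludes 0, was met. As written it would have argued against leukocytes as the whole cause. For the reasons above, the test was judged afterwards to be unable to decide. Some single leukocyte genes were higher by more than the interferon median, with log2 ratios of 1.77 for Ptprc and 1.20 for Ctss. The neutrophil gene S100a9, which is not among the 14, was at 2.03. Most of the 14 lay below the interferon median, as did all 12 macrophage markers, of which Fcgr1 was the highest at 1.03. Of the 67 interferon genes, 39 lay above that highest macrophage marker. A part of the pattern or more may still come from leukocytes, and particular kinds of them stay open. Reads shared between near-identical copies are argued against by the 38 members outside such families, with a median of 1.06 (0.82 to 1.17). The sex of the hearts cannot be told apart from the mimic, since 4 Y-linked genes were listed at 0 in only 1 library, and the difference between 2 single animals and a mixed-up sample, which was not tested, stay open as well.

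The second pattern is the lower white adipocyte genes, for which a candidate explanation is less fat tissue attached to the CHAPIR mimic heart. A limit written before the values were seen, a median above -0.5 over 10 other fat-cell genes with an interval above -1, was met at -0.059 (-0.59 to 0.16), which as written would have argued against it. After the values were seen that limit was judged wrong, because these genes stayed at a median of 10.2 FPKM in the CHAPIR library against a median drop of 3.65 FPKM over the 11 measured adipocyte markers, so other cells of the heart may express them and hide a loss of fat. The drop of Car3, 43.6 FPKM, was far above that level, and of the 10 genes Pck1 (0.29 against 6.78 FPKM) and Gpd1 (15.6 against 30.9 FPKM) were lower, so less fat tissue cannot be told apart here from a change within fat cells, whether from the mimic, sex or the single animals. Lower lipid synthesis in heart cells with equal fat was expected to leave the 9 markers outside lipid synthesis above a median of -0.5. It was also expected to lower the median of 12 other lipid synthesis genes by 1.5-fold or more. Neither was seen, since the medians were -1.29 and -0.20, and 6 of the 9 markers were lower by 1 log2 unit or more. The limit for arguing against it, an interval of the 9 markers below -0.5, was not met either. That interval, -1.91 to -0.16, reaches close to 0, so the test does not decide.

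The third pattern is the 2-fold differences of single genes outside the lists, such as Mipep and Rer1, for which reads moved between listed and unlisted transcripts of a gene are a candidate explanation. Among genes outside the lists with a mean of at least 5 FPKM, the share of 2-fold genes was 2.10% of 5673 genes with several annotated transcripts and 2.23% of 448 genes with 1, a ratio of 0.940 (0.54 to 2.23). This cannot be told apart from a difference of the genes themselves, because only 10 genes of the second kind passed 2-fold and the interval spans the ratio of 2 that would have pointed to reassignment.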
